A study of Mus musculus with 16 samples.

How the data were processed

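The series holds 16 libraries from mouse bone-marrow-derived macrophages, which are macrophages grown from marrow cells in the presence of the growth factor M-CSF. Per the labels' protocols, cells were cultured for 7 days with M-CSF at 50 ng per ml, and lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, was given for 6 or 24 h. The RNA-seq libraries number 6, with 3 untreated and 3 LPS. The RiboTag libraries number 6, with 2 untreated, 2 at 6 h of LPS and 2 at 24 h of LPS. The ribosome profiling libraries number 4, with 2 untreated and 2 LPS. The LPS duration of the RNA-seq and ribosome profiling libraries is not given per sample in the sources used here.

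The file used here was deposited as a gene annotation in GTF format, with 1544831 lines and 115521 transcripts. Each line places an exon, a coding sequence (CDS), a codon, an untranslated region or a transcript on a chromosome, with start and end positions counted from 1. No line carries a value in the score column, and 0 columns hold values per sample. The planned comparisons of LPS with untreated libraries, and of ribosome profiling with RNA-seq, were therefore not run, and library values and their depth were not analysed here. TopHat2 version 2.1.1, a spliced read aligner, and the build mm10 are named per the submitters' processing notes. How the authors assembled the annotation and at which step they used it is not given in the sources used here. The effect of shared exons on read counts was not measured.

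Gene models were read with Python 3.11.15 and pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Lines were assigned to Ensembl when their source was ensembl, havana, ensembl_havana, insdc or mirbase, and otherwise kept the source RefSeq or unknown given in the file. Models of these last sources are called added models. Ensembl biotypes were grouped into protein-coding, long non-coding (lincRNA, antisense, processed transcript, sense intronic, sense overlapping and a few rarer kinds), pseudogene, TEC (models awaiting experimental evidence), small RNA and immune receptor segments. The non-coding set joined long non-coding, pseudogene, TEC and small RNA models. Added models carry no biotype and stayed outside these classes. Spliced length was the sum of exon lengths of a gene's longest transcript. Over all protein-coding genes, CDS lengths in codons were taken from Ensembl transcripts with both start and stop codon lines, without the stop codon. For genes of the lists they came from the longest CDS of any transcript, complete or not. The 5′ untranslated length was taken from the complete transcript with the longest CDS.

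Position was described by overlap of the non-coding gene's span with a protein-coding gene's span by at least 1 base, with same-strand overlap taking precedence. Exon sharing was the number of bases of a gene's merged exons covered by exons of another gene on the same strand, and a gene with over 50% of its exon bases shared was called mostly shared. Shares carry Wilson 95% confidence intervals, which treat gene models as a sample and cover counting error only. Genes are not replicates, and no p-value was computed between gene classes. Symbols were compared with a table that pairs gene IDs with symbols, in which 45143 of the 46078 Ensembl IDs were found and 3464 had another symbol than in the annotation. A RefSeq gene table of assembly GRCm38.p6 supplied synonyms and biotypes, and its coordinates were used only to check overlap.

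The distance of 2 gene lists to long non-coding genes was set against 10000 random lists of protein-coding genes on chromosomes 1 to 19, X and Y, drawn from 20 bins of coding gene density within 500000 bases or, as a second match, of transcripts per gene. The test was one-sided and its 4 p-values were adjusted by Benjamini-Hochberg. The code was tested on simulated gene models. Shared exon bases were exact in 100% of 4200 genes, the position class was right in 200 of 200 planted overlaps and intron sets were matched in 67 of 67 planted copies. The random-list permutation test gave p = 0.0005 for a planted list of 30 genes against 2000 random lists, the smallest value that number of lists can give. Every planted gene had a target within 200 bases of its start, so this does not measure power for smaller shifts. Of 100 lists without a planted shift, 5 gave p under 0.05 in the same test, against 200 random lists each. Their genes were drawn at random, and lists of neighbouring genes were not simulated.

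The lists of genes to name, the descriptive results and their alternatives were fixed before the data were examined. By that rule about 30 genes are named in list order, long non-coding RNAs first, followed by LPS response genes, together with the top 3 models by spliced length, transcripts and exons. A member that no gene model names is given as not found under that symbol. Other genes named were chosen after their values were seen. The exon sharing of the interferon-stimulated genes is not reported here. The comparison of added with Ensembl models, short coding sequences and the RefSeq biotype of long non-coding models were also chosen after seeing the data. Alternatives covered the chromosomes used, automatic models, pseudogenes, the overlap rule and the transcript taken per gene. The search for open reading frames in non-coding transcripts needs genome sequence, which was not used here.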

Results

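The libraries addressed which RNAs are translated in macrophages before and after LPS, including RNAs annotated as non-coding. RNA-seq measured total RNA in 3 untreated and 3 LPS samples. RiboTag, in which a tagged ribosomal protein expressed in LysM-Cre cells is immunoprecipitated to recover ribosome-bound RNA, covered 2 untreated samples, 2 samples at 6 h of LPS and 2 at 24 h. Ribosome profiling, which sequences the fragments protected by ribosomes, covered 2 untreated and 2 LPS samples. Library values were not analysed here, so no gene is described as changed by LPS and the depth is unknown. The results below describe the gene models on which such libraries are read, in build mm10.

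The annotation placed 50578 genes. Ensembl sources contributed 46078 genes and 110379 transcripts. RefSeq lines contributed 4097 genes and 4631 transcripts, and lines of unknown source 403 genes and 511 transcripts. Of the 4500 added genes, 2100 carried a CDS. Among Ensembl genes, 22159 were protein-coding, 6497 long non-coding, 8839 pseudogenes, 6195 small RNAs, 1895 TEC models and 493 immune receptor segments. The long non-coding class held 3413 lincRNAs, 2068 antisense genes, 752 processed transcripts, 239 sense intronic and 22 sense overlapping genes. Leaving out Ensembl's automatic models lowered the small RNAs from 6195 to 1250.

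The longest spliced models were the muscle protein gene Ttn at 106824 bases, the imprinted antisense RNA Kcnq1ot1 at 84395 bases and the TEC model Gm37985 at 74456 bases. Tcf4 had 59 transcripts, Ank3 44 and Pcdh15 41. Ttn had 347 exons in its most exon-rich transcript, Neb 157 and Col7a1 119.

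Long non-coding genes were shorter and had fewer exons than protein-coding genes. Their median spliced length was 968 bases (quartiles 581 and 1933, n = 6497), against 2549 bases (quartiles 1382 and 4028, n = 22159) for protein-coding genes. The median exon number was 3 (quartiles 2 and 4) against 7 (quartiles 3 and 13), and the median number of transcripts 1 (quartiles 1 and 2) against 2 (quartiles 1 and 5). With the median over a gene's transcripts in place of the longest, the spliced lengths were 816.5 and 1472 bases, so the size of this difference depended on the transcript taken. Within protein-coding genes, 27481 of 82460 transcripts (33.3%) had no CDS, mainly retained introns (15472) and processed transcripts (11960).

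Coding regions in non-coding gene models came from 1 biotype. Of 23426 non-coding Ensembl genes, 19 carried a CDS (0.0811%, 95% interval 0.0519 to 0.127%), and all 19 were polymorphic pseudogenes, of which 13 had a transcript of coding biotype. None of the 6497 long non-coding genes had one, which follows from biotypes given to genes without a CDS and does not measure translation. A CDS of an added model lay over exons of 314 non-coding genes on the same strand (1.34%). Of these, 251 were pseudogenes (2.84% of 8839), 47 of them with an identical intron. Over all 8839 pseudogenes, 6830 (77.3%) had a single exon and could not have such an intron. A CDS of an added model lay over exons of 51 long non-coding genes (0.785%, 95% interval 0.598 to 1.03%). In 32 of them the 2 models had an identical intron. In 16 of the 51 the added transcript had a curated (NM) identifier and in 35 a predicted (XM) one. Of the 51, 18 were lincRNAs on chromosome Y under predicted models, and none of these 18 had an identical intron. Some of them, such as Gm21529, could not have one. In Gm21529 the CDS lay over 528 exon bases, its whole span, which leaves no intron. Examples with curated models and identical introns, chosen after the values were seen, were the antisense genes Grin1os, where the RefSeq-source model E130003G02Rik placed a CDS of 462 bases, and Csmd2os, where 4930465A12Rik placed one of 429 bases.

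Among protein-coding genes, 605 of 21598 with a complete CDS (2.80%, 95% interval 2.59 to 3.03%) had a longest CDS of at most 100 codons. The median was 395 codons (quartiles 257 and 652).

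**Figure D1:**
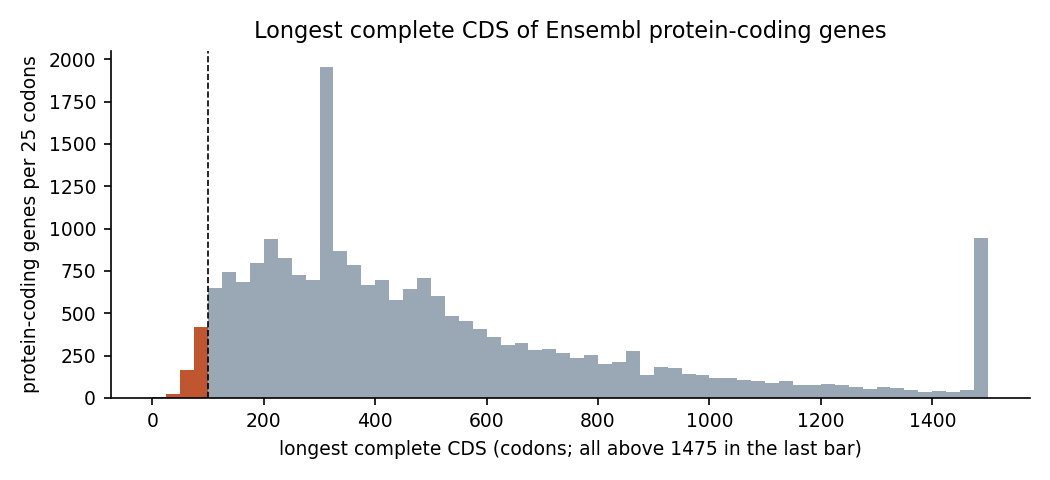
Number of Ensembl protein-coding genes per 25 codons of longest complete CDS, with genes of at most 100 codons in orange and a dashed line at 100. Those 605 genes form the left edge, and all genes above 1475 codons are collected in the last bar.

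Non-coding genes often lay within or across protein-coding genes. Of the 23426, 3869 (16.5%, 95% interval 16.05 to 16.997%) overlapped a protein-coding span on the same strand, 4769 (20.4%, 95% interval 19.8 to 20.9%) only on the opposite strand and 14788 (63.1%) not at all. Antisense genes overlapped on the opposite strand in 84.7% of cases, and lincRNAs had no overlap in 85.7%. Sense intronic genes overlapped on the same strand in 94.98% and TEC models in 45.9%. The names antisense, lincRNA (long intergenic) and sense intronic describe position, so the shares of these biotypes largely follow from the labels. The share with any overlap fell from 36.9% to 11.2% when exon bases rather than spans had to overlap. For long non-coding genes, exons overlapped exons of protein-coding genes on the same strand in 120 genes (1.85%) and on the opposite strand only in 1667 (25.7%). Whether reads were counted by strand is not given in the sources used here. Without strand, unspliced reads lying wholly within the overlapping bases of these 1667 genes could not be assigned to either gene by position. Reads from the other bases of these exons are not affected by this overlap, and the number of overlapping bases per gene is not given here. The start of a long non-coding gene lay a median of 28583 bases from the nearest protein-coding start (quartiles 4104 and 97630, n = 6495), and 1090 genes (16.8%) started within 1000 bases of one.

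**Figure D2:**
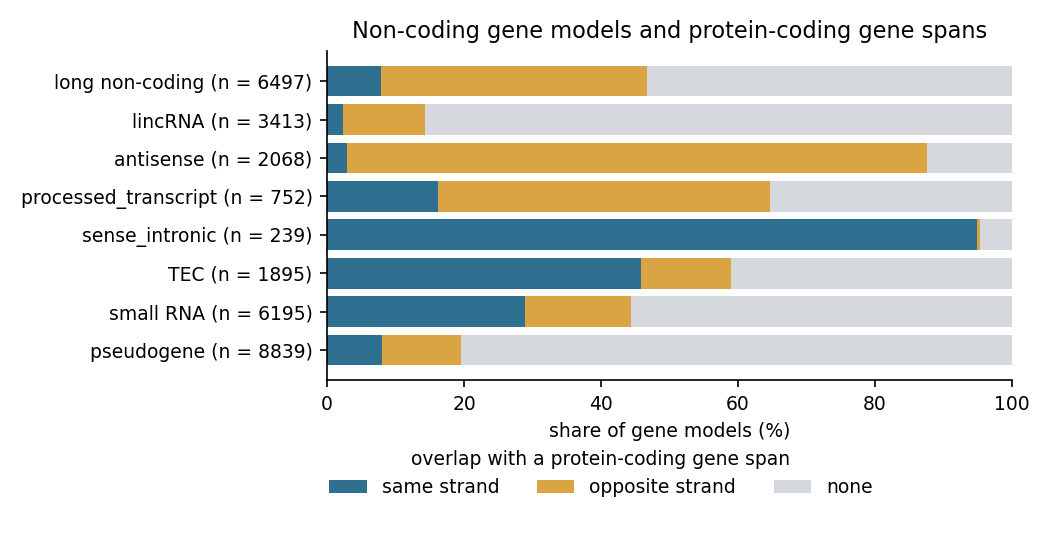
Share of non-coding gene models (percent, horizontal axis) whose span overlaps a protein-coding gene span by at least 1 base on the same strand, only on the opposite strand, or not at all, by class and biotype with the number of models. Antisense genes reach 84.7% on the opposite strand and sense intronic genes 94.98% on the same strand, positions that these biotype names describe.

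The long non-coding list held 32 symbols, of which 24 named a gene model. Morrbid, Mirt1, Mirt2, Snhg15, Lncenc1, Epb41l4aos, Pint and Lncpint were not found under that symbol. Morrbid matched Gm14005, itself a listed symbol, and Pint matched the model Lincpint. With models matched through the symbol tables the list covered 32 gene models, of which 31 had no CDS. These include a second model for both Nron and Meg3. By position, 24 of the 32 overlapped no protein-coding span, 7 overlapped one on the opposite strand only and 1 on the same strand.

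AW112010 was a lincRNA on the minus strand of chromosome 19, from 11047617 to 11050566, with 1 transcript of 3 exons and 770 bases. It had no CDS and no overlap with a protein-coding gene, and its start lay 30536 bases from that of Ms4a8a. The RefSeq gene table also listed it as a long non-coding RNA. At the Ptgs2 locus, which encodes the prostaglandin synthase COX-2, Ptgs2os lay on chromosome 1 from 150074873 to 150099963 on the minus strand, and its start was 68 bases from that of Ptgs2 on the plus strand. Ptgs2os2, a lincRNA with 2 exons and 1745 bases from 150159043 to 150164948, started 64917 bases from Ptgs2. Ttc39aos1, an antisense gene on chromosome 4 from 109403794 to 109406155, started 468 bases from Ttc39a.

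**Figure D3:**
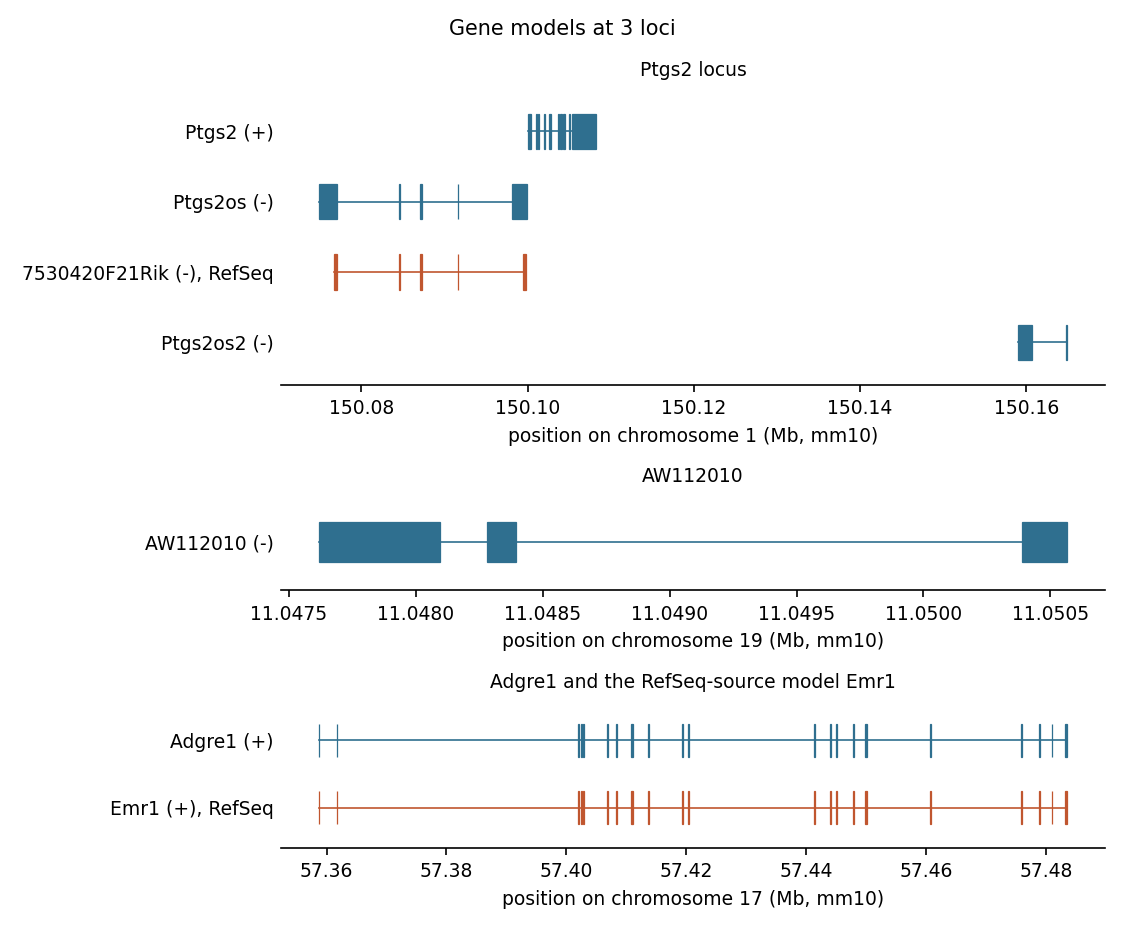
Exons (boxes) and spans (lines) of gene models at the Ptgs2, AW112010 and Adgre1 loci against chromosome position in Mb, with Ensembl models in blue, RefSeq-source models in orange and strands in brackets. Ptgs2os starts 68 bases from Ptgs2, and Emr1 covers all 3245 exon bases of Adgre1.

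Of the 32 listed models, 13 shared exon bases with small RNA genes. Among them were Gas5 with 10 small RNA genes, Mir17hg with 6, and Neat1, Snhg12 and Meg3 with 3 each. Snhg5 shared bases with 2, and Malat1 and F630028O10Rik with 1 each. For Nron, also among the 13, the small RNA gene was its own second model. Some of the 13, such as Mir17hg and Snhg12, bear host gene names, so the count partly follows from the choice of list. The share over all long non-coding genes is not given here. Malat1 and Neat1, abundant nuclear RNAs, were lincRNAs on chromosome 19 with longest transcripts of 6983 and 20771 bases. Gas5, from 161034422 to 161038539 on chromosome 1, had 25 transcripts and overlapped Zbtb37 on the opposite strand. Gm14005 (Morrbid), Gm12840, 1500012K07Rik and the RNA component Rmrp shared no exon base with another gene. Rmrp lay opposite Ccdc107, 1500012K07Rik opposite Sv2b and Kcnq1ot1 opposite Kcnq1. Meg3 was a lincRNA on chromosome 12 from 109541001 to 109571726, but a second model of that name on a patch sequence was protein-coding with a CDS of 462 bases.

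Other listed RNAs shared part or all of their exon bases with another long gene model. Trp53cor1 shared all 2956 of its exon bases with the RefSeq-source model Gm16197, and the antisense model of Nron all 3653 with A630071L07Rik. Mir22hg shared 1752 bases with 2210403K04Rik and 91.1% of its exon bases in all, and Bvht 588 bases with LOC545261, or 84.1%. The share was smaller for Ptgs2os, with 1098 bases (25.4%) shared with 7530420F21Rik, and for Dleu2, with 1237 bases shared with Gm20034 and 11.03% in all. Under its own symbol, Mir155hg, the host of miR-155, was present only as a model of unknown source on chromosome 16 from 84713023 to 84715244. All 1263 of its exon bases were shared with the Ensembl gene Gm26667, so an Ensembl model also covers it under another name. Snhg1 was present only as a RefSeq-source model, with 10 exons and 476 bases.

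All 26 LPS response genes were found, on 12 chromosomes, as protein-coding models with 1 to 6 transcripts and a longest CDS of 91 to 1144 codons. None shared an exon base with another gene on the same strand. The cytokine genes Il6 and Tnf lay on chromosome 5 from 30013114 to 30019981 and on chromosome 17 from 35199381 to 35202007, with a CDS of 211 and 235 codons. Il1b and Il1a lay on chromosome 2 with a CDS of 269 and 270 codons, Il12a on chromosome 3 with 236 and Il12b on chromosome 11 with 335. Acod1 was listed under its older symbol Irg1. Of the 10 LPS receptor pathway genes, 1 shared exon bases on the same strand, Irak1 (141 bases, 2.99%). Of the 10 macrophage identity genes, 2 were mostly shared. Adgre1, which encodes the macrophage marker F4/80, shared all 3245 exon bases with the RefSeq-source model Emr1, and Spi1, which encodes the transcription factor PU.1, shared 72.2%, mainly with Sfpi1 (1333 bases). Of 8 genes marking other cell types, 1 was mostly shared, Hbb-bs with the model Beta-s (628 bases, 72.8%). These genes were named after their values were seen.

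The list of small proteins found in transcripts once annotated as non-coding, and of their host genes, held 19 symbols, of which 10 named a gene model. Some members, such as Sln and Pln, are protein-coding models here, and membership does not date their annotation. Uqcc6 and Erln were not found under those symbols or a listed synonym. The list matched 15 models, 9 with a CDS and 6 without. The models without a CDS were Mrln, Tunar, Gm34302 (Strit1), 5430416O09Rik (Spaar), 2210013O21Rik (Nbdy) and 2310009A05Rik (Pigbos1). The RefSeq gene table, matched by symbol or synonym, listed 5 of these 6 as protein-coding and Tunar as long non-coding. Among those with a CDS, the calcium pump regulators Sln and Pln had 31 and 52 codons, and Smim6 had 56. Of the 6497 long non-coding genes, 3028 matched the same table by symbol alone. It listed 93 of these 3028 as protein-coding (3.07%, 95% interval 2.51 to 3.75%), and 92 of the 93 overlapped their position in it. Such listings were not particular to long non-coding genes. Matched the same way, they covered 326 of 5788 pseudogenes (5.63%), 7 of 75 TEC models (9.33%) and 0 of 3787 small RNAs. For 5 of the 93 an Ensembl protein-coding model bore the same symbol, so that the listing may belong to that model. The 93 were not chosen for a short CDS, and their number does not count small proteins. They included 5830428H23Rik, now Zfp950, where the added model Zfp950 carried a CDS of 1827 bases. With the symbols of the annotation itself the count was 74 of 2728 (2.71%), and with synonyms that belong to 1 gene of the table it was 120 of 3087 (3.89%).

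The added models overlapped Ensembl genes extensively. Of 4500 added models, 2652 (58.9%, 95% interval 57.5 to 60.4%) shared at least 1 exon base with an Ensembl gene on the same strand, and 2299 (51.1%) shared at least 90% of their exon bases. Among protein-coding genes, 334 (1.51%, 95% interval 1.36 to 1.68%) had over 50% of their exon bases shared when only Ensembl models were compared, and 1651 (7.45%, 95% interval 7.11 to 7.80%) when all models were. For long non-coding genes these counts were 70 (1.08%) and 412 (6.34%). The shared part of all protein-coding exon bases was 1.39% among Ensembl models and 6.22% among all models.

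**Figure D4:**
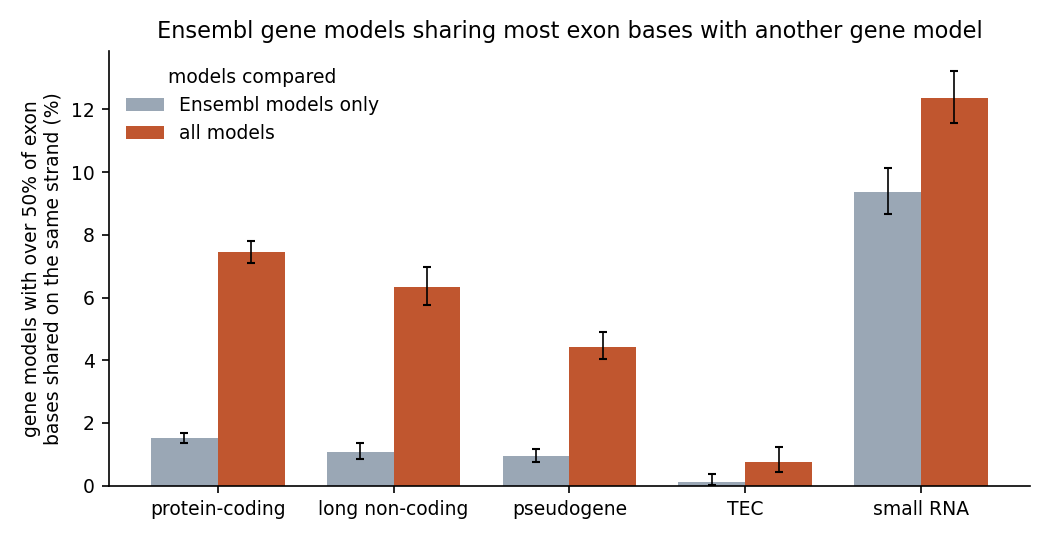
Share of Ensembl gene models (percent) in each class with over 50% of their exon bases covered by another gene on the same strand, compared with Ensembl models only (grey) and with all models (orange); bars carry Wilson 95% intervals. Protein-coding genes go from 1.51% to 7.45% and long non-coding genes from 1.08% to 6.34%.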

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

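Other settings were chosen before the data were examined, except that those for added models, short coding sequences and RefSeq biotypes, the count of added CDS and the long non-coding subset were chosen after seeing the data. Over 31 alternative values, 17 stayed within the tolerance and 14 moved, where the tolerance was 1.5 times for a count and the 95% interval of the reported value for a share or median. The 19 non-coding genes with a CDS became 0 without pseudogenes, since all 19 are polymorphic pseudogenes, and 329 when a CDS of an added model on the same strand was also counted. The share of non-coding genes overlapping a protein-coding gene, 36.9%, became 11.2% for exon overlap, 32.5% when at least 50% of the span had to overlap, 47.3% without pseudogenes and 46.7% for long non-coding genes alone; each follows from the stricter rule or the smaller set. The share of added models sharing exon bases, 58.9%, became 56.3% at 50% of their exon bases, 51.1% at 90%, 43.0% with an identical intron and 72.3% on either strand. Protein-coding genes with over 50% of exon bases shared fell from 1651 to 334 among Ensembl models only, since the added models are then left out. The total of 50578 genes stayed within 1.5 times on chromosomes 1 to 19, X and Y and without automatic models.

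No paired analysis was possible because no value per library was analysed here. For the same reason the other settings intended for the RNA-seq, RiboTag and ribosome profiling comparisons were not run, and those of the open reading frame search were not run without genome sequence. Depth sets no limit on these counts of gene models, and how many reads fall in shared exons stays unknown.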

Other observations

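The tests of the added models, the values on coding sequence length, untranslated regions, shared names and Mx1 were chosen only after the results were seen; the tests of distance to long non-coding genes were set before theirs.

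The list on the integrated stress response held 6 genes. Among Atf4, Atf5, Ddit3 and Ppp1r15a, known for upstream frames in their 5′ untranslated regions, Ppp1r15a had a 5′ untranslated region of 764 bases, longer than in 97.4% of 21598 protein-coding genes with a complete CDS, Atf4 had 594 bases (95.05%) and Atf5 373 bases (85.6%). Ddit3 had 186 bases, and Eif2ak2 and Eif2ak3, kinases that start the response, had 190 and 211. All 6 lay above the median of 134 bases, but only 3 above the upper quartile of 264 bases, and the list was not tested against other lists. Mx1, an antiviral GTPase gene, carried a CDS of 1881 bases as a protein-coding model, while the RefSeq gene table listed it as a transcribed pseudogene. The model named Apela, a gene known for a short secreted peptide, carried a CDS of 461 codons and shared 3128 exon bases with other models, of which 2156 with Trim61.

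The number of protein-coding genes by longest complete CDS was 162 at 51 to 75 codons, 417 at 76 to 100, 648 at 101 to 125 and 743 at 126 to 150. In windows of 5 codons it was 95 at 91 to 95, 100 at 96 to 100, 146 at 101 to 105, 107 at 106 to 110 and 135 at 111 to 115. The peak of 1953 genes at 301 to 325 codons held 999 genes with olfactory receptor names (51.2%). Names carried by both a protein-coding and a long non-coding Ensembl gene numbered 8, among them Meg3, Lhb and Tmem134. The annotation named 9 scaffolds under both of 2 naming manners, with 11 genes on the sequences named in the manner of the UCSC browser.

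One hypothesis was that long non-coding genes are annotated closer to LPS response genes than to other coding genes of like gene density. The 26 genes had a median distance of 68028 bases between starts, against a median of 112227 bases over 10000 random lists matched on coding gene density, of which 95% lay between 53507 and 215113. A one-sided permutation p of 0.0897 (adjusted p = 0.179 over 4 tests) missed the bound of 0.05 set beforehand, and matching on transcripts per gene gave p = 0.0714 (adjusted p = 0.179). The observed median lay inside the range of the random lists, so a difference of this size or smaller is not excluded. The list held only 26 genes, some of which are neighbours such as Cxcl1 and Cxcl2. The closest pairs were Ptgs2 with Ptgs2os at 68 bases, Il1b with Il1bos at 1242 and Il6 with RP24-418J2.4 at 4316.

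For interferon-stimulated genes the same test gave no sign of a shorter distance, but it could not decide the hypothesis. The 13 genes had a median of 129725 bases, with a one-sided permutation p of 0.599 (adjusted p = 0.616 over 4 tests). Random lists matched on coding gene density had a median of 114748 bases, and 95% of them lay between 38412 and 283246. With so wide a range for 13 genes, a shorter distance is not excluded. Some of the genes are also neighbours, such as Ifit1, Ifit2 and Ifit3, which had the same nearest long non-coding gene, Gm26902. Of the 13 genes, Oasl1 was the closest, 37 bases from the antisense gene Gm13822.

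Added models share exon bases with Ensembl models, and a candidate explanation is that many are the same gene under an older symbol. Of the 2652 sharing models, 54.7% (95% interval 52.8 to 56.6%) bore a name that RefSeq lists as a synonym of the partner's symbol, such as Emr1 for Adgre1 and Sfpi1 for Spi1, and a further 11.6% bore the partner's symbol in the symbol tables. Another candidate explanation is that different genes happen to overlap. An identical intron was found in 94.1% of 2248 overlapping spliced pairs of added with Ensembl models. That share was higher than among pairs of Ensembl genes, where it was 72.0% of 1136. Since most overlapping pairs of Ensembl genes also had an identical intron, it cannot tell the same gene from different genes. Over all 2652 sharing models 1936 (73.0%) had an identical intron. Of the other 716, 638 were unspliced or had only unspliced partners. By introns alone, overlap of different genes stays open for models with and without an identical intron. The 27.5% of sharing models whose names are not in the RefSeq table stay open. Another 167 models (6.30%, 95% interval 5.43 to 7.29%) bore a symbol or synonym of another gene. Their names do not point to a shared identity, but a name alone cannot decide it, since either model could bear the wrong symbol. No biological explanation was tested.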
